A study of Citrullus lanatus with 6 samples.

How the data were processed

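ClNAC56, a NAC-family transcription factor of watermelon (Citrullus lanatus), was studied by DNA affinity purification sequencing (DAP-seq). In this assay a protein made in vitro is mixed with a library of naked genomic DNA fragments, the bound fragments are recovered and sequenced, and places with an excess of fragments are called as peaks. The labels list 6 samples of genomic DNA from leaves, 3 with the ClNAC56 protein and 3 with MBP (maltose-binding protein) as the control. The titles of a pair of MBP samples differ only by a suffix, and whether these are separate libraries is not stated. The DNA carries no chromatin proteins of the living cell, so a peak is at most evidence that the protein can bind there in vitro.

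The deposited values are peak lists on 3 sheets named T1, T2 and T3. Per the submitters' processing notes, Bowtie2, Picard, MACS2 and bedtools were used. Their versions, parameters and order, and the genome build, are not given in the sources used here. The sequences are named Cla97Chr01 to Cla97Chr11 and Cla97Scf, and positions are given as in the lists. No label ties a sheet to a library or states whether a list came from a single library or from pooled libraries. The lists were read as ClNAC56 peaks because the stated aim of the series is ClNAC56 binding and MBP is labelled as the control. No peak list of the MBP libraries was analysed here.

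Per the file headers, each peak has a start, an end, a summit, a pileup signal at the summit and a fold enrichment ratio. The headers of the remaining value columns were damaged by a spreadsheet. They were read as the −log10 p and −log10 q that the authors deposited, because the order of columns is that of a MACS2 table and because the former exceeds the latter in each peak of lists T2 and T3. Fold enrichment and q are the authors' own values per peak and are used to describe, rank and filter peaks. The total depth of the libraries is unknown.

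Sheets T1 and T3 were identical in all 3288 rows, and all peak names on sheet T1 start with T3, so they were counted as 1 list. This left 2 distinct lists, T2 and T3. With no label for the libraries behind them, no mean or standard deviation over libraries was computed.

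Some quantities were recovered from the deposited values. The pileup signals of each list are whole multiples of a constant, 0.224 in list T2 and 0.245 in list T3, for 100% of peaks within a tolerance of 0.0051. The whole multiple was taken as the number of fragments over the summit. The background was computed as (pileup + 1) / fold − 1, the form in which MACS2 adds 1 to both parts of the ratio. It is therefore on the scale of the pileup, while a fragment number is the pileup divided by the constant. In each list, all of the backgrounds came out as 1 recurring minimum, as a whole number, or as a whole number of fragments in 1 kb or in 10 kb scaled to the shortest peak width of the list, 304 bp in T2 and 299 bp in T3. The tolerance was 0.2% of the value for the minimum and for whole numbers, at most 0.05 of a count for 1 kb and 0.12 for 10 kb, which 24% of random values would meet. If the constant is the factor by which the caller scaled the ClNAC56 library down to its control, the ClNAC56 library was 4.47 times the size of its control behind list T2 and 4.08 times behind list T3. Intervals on fragment numbers treat fragments as independent counts, and intervals on shares treat peaks as independent. Neither covers error between libraries. Reads from amplified libraries are not independent molecules, so the intervals on fragment numbers may be too narrow.

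Peaks were called shared when they overlapped by at least 1 bp. Chance overlap came from 1000 random placements of a list's peaks on the same sequences, taking the last peak end of both lists as the length of a sequence, with a one-sided p. Consensus peaks are the merged intervals that hold a peak of each distinct list. Fold enrichment was compared across shared peaks with Spearman and Pearson correlations and permutation p-values from 100000 resamples. Shared and single-list peaks were compared by the difference of medians with two-sided permutation tests of 100000 resamples, with Benjamini-Hochberg adjustment over 8 tests. Peaks are not independent replicates, so these p-values describe these lists only. Shares have 95% Wilson intervals. The named peaks follow a rule fixed before the data were examined, namely the 10 consensus peaks with the highest value of the lower of the fold enrichments in T2 and T3.

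Alternatives fixed before the data were examined were stricter limits on q and fold for the number of peaks, reciprocal 50% overlap, summits within 100 bp, a stricter limit on q and assembled chromosomes only for the overlap, the union of lists, reciprocal 50% overlap, a stricter limit on fold and leaving out each list for the consensus, and leaving out the highest 1% of folds for the correlation. The use of these settings for the comparison of shared with single-list peaks, and reciprocal 50% overlap for the correlation, were added after seeing the data, as was the T3 to T2 fold ratio by quartile. Placement within 500 kb of a peak's own position, fragment numbers in place of folds, removal of peaks with a background over 10 times the lowest, and other rankings of the named peaks were added after seeing the data. On simulated data with 59.1% of the 3288 peaks of list T3 kept in place, the overlap step found 59.2%. With no peak kept, it found 0.821% against 0.762% in random placements. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The planned tests of sequence motifs, of positions relative to genes and of lists of target genes need the genome sequence and gene annotation, which were not used here, so peaks are named by position only.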

Results

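The series examined where ClNAC56, a NAC transcription factor of watermelon, binds naked leaf genomic DNA, using 3 samples made with the ClNAC56 protein and 3 made with MBP, a protein used as the control. The comparisons below concern the 2 distinct deposited peak lists, T2 and T3, and each fold enrichment is the authors' value of the pileup at a peak's summit over the caller's background. Which library stands behind each list is not given, so differences between the lists have no error from replicate libraries. The depth was known only in relative terms. The median peak rested on 135 fragments at its summit in list T2 and 123 in list T3, and the peak with the fewest rested on 51 and 47 fragments.

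ClNAC56 peaks numbered 2846 in list T2 and 3288 in list T3. They were narrow, with a median width of 379 bp in T2 and 380 bp in T3, and covered 1157877 and 1337775 bp. Enrichment was moderate at most sites. The median fold enrichment was 5.82 in T2 (interquartile range 4.81 to 7.56) and 5.93 in T3 (4.82 to 7.74). A fold of 10 or more was reached by 320 peaks (11.2%) in T2 and 431 peaks (13.1%) in T3, and the maximum was 57.2 in T2 and 78.1 in T3. The largest q among the deposited peaks was 0.0427 in T2 and 0.0397 in T3.

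The first comparison asked how far both lists place ClNAC56 at the same sites. Of the peaks in list T2, 2490 (87.5%, 95% Wilson interval 86.2 to 88.7) overlapped a peak of list T3, and 356 did not. Of the peaks in list T3, 2488 (75.7%, 74.2 to 77.1) overlapped a peak of list T2, and 800 did not. Random placement on the same sequences gave a mean of 21.1 shared peaks for T2 (0.740%) and 21.0 for T3 (0.639%), and the maximum of 1000 placements was 39 for each (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Moving the peaks by up to 500 kb, which keeps their regional density, gave a mean of 49.9 shared peaks for T2 and 48.7 for T3. Neither kind of placement allows for a background shared by both lists, so part of the overlap above these values may come from it. Whether the lists share ClNAC56 reads is not known either, since pooling of libraries is not stated. The overlap is therefore not shown to be agreement between separate libraries. The summits of the 2490 overlapping pairs lay a median of 7 bp apart, and 2442 pairs (98.1%) had summits within 100 bp. Merging gave 2488 consensus sites, which were 68.3% of the 3644 separate intervals in the union of the lists.

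The overlap depended on peak strength. Each of the 712 peaks in the strongest quartile of T2 and each of the 822 in the strongest quartile of T3 was shared (lower limits of the 95% Wilson intervals 99.5% and 99.5%). In the weakest quartile, 69.3% of T2 peaks (65.8 to 72.6) and 49.1% of T3 peaks (45.7 to 52.5) were shared. All 320 T2 peaks and all 431 T3 peaks with a fold of 10 or more were found in the other list. Single-list peaks had a median fold of 4.59 against 6.11 for shared peaks in T2, and of 4.76 against 6.53 in T3. They were also narrower, with a median width of 327.5 bp against 386 bp in T2 and 327 bp against 402 bp in T3. For each of these 4 differences the permutation p was 1e-05, the smallest that 100000 resamples can give, and the adjusted p was 1.33e-05. The lower folds are partly built in, because a single-list peak was not called in the other list and the folds of the lists correlate. Width has a minimum of 304 bp in T2 and 299 bp in T3 and was not tested apart from fold. The narrower widths are therefore no separate support. The background at the summit was not shown to differ between single-list and shared peaks, with single-list medians lower by a difference of -0.104 in T2 (adjusted permutation p = 0.31) and of -0.0366 in T3 (adjusted permutation p = 0.194).

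**Figure D1:**
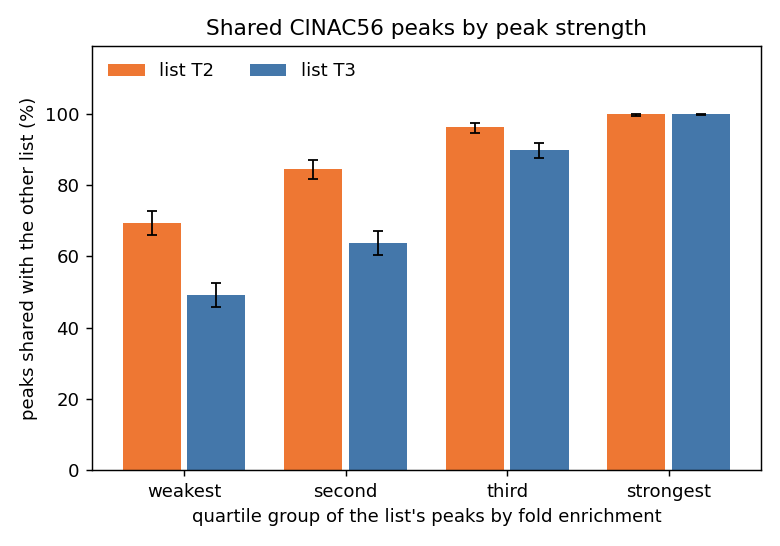
Percent of peaks that overlap a peak of the other list by at least 1 bp (y axis), in each quartile of the peaks ranked by fold enrichment (x axis), for lists T2 and T3. Bars start at 0 and the lines are 95% Wilson intervals; the share climbs from 69.3% and 49.1% in the weakest quartile to 100% in the strongest.

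The second comparison asked whether sites strongly bound in one list were strongly bound in the other. Across the 2490 overlapping pairs, Spearman's rho of the fold enrichments was 0.922 and Pearson's r of their log2 values was 0.955 (permutation p = 1e-05 for each). The folds lay within a factor of 1.5 of each other at 98.2% of pairs. The background entering both folds was nearly the same (rho = 0.980 over the 2468 pairs with a background of at most 10 times the lowest), so part of this correlation may come from the shared background. Over these 2468 pairs rho was 0.920. It was 0.288 when the pileups were reshuffled among peaks and each peak kept its background, and the covariance of the log2 folds was 0.350 against 0.182 after reshuffling. Reshuffling also broke any link between a peak's pileup and its own background. The reshuffled values therefore do not measure the part due to the shared background. The fragment numbers at the summits, which contain no control value, had a rho of 0.949. They can still carry local coverage common to both lists, so this rho is not free of the background. Nor is it known whether the lists share ClNAC56 reads, which would raise each of these correlations.

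Folds were higher in list T3 at 1760 of the 2490 pairs (70.7%), with a median T3 to T2 ratio of 1.08. The ratio grew with peak strength among pairs called in both lists. It was 1.04 (bootstrap 95% interval 1.02 to 1.05) in the weakest quartile of pairs by geometric mean fold, 1.05 (1.04 to 1.07) and 1.08 (1.06 to 1.09) in the middle quartiles, and 1.14 (1.13 to 1.16) in the strongest quartile, where 85.2% of pairs were higher in T3. These intervals resample peaks and hold no error between libraries. Single-list peaks have no ratio and were weaker than shared peaks, so their absence may account for part of the rise.

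**Figure D2:**
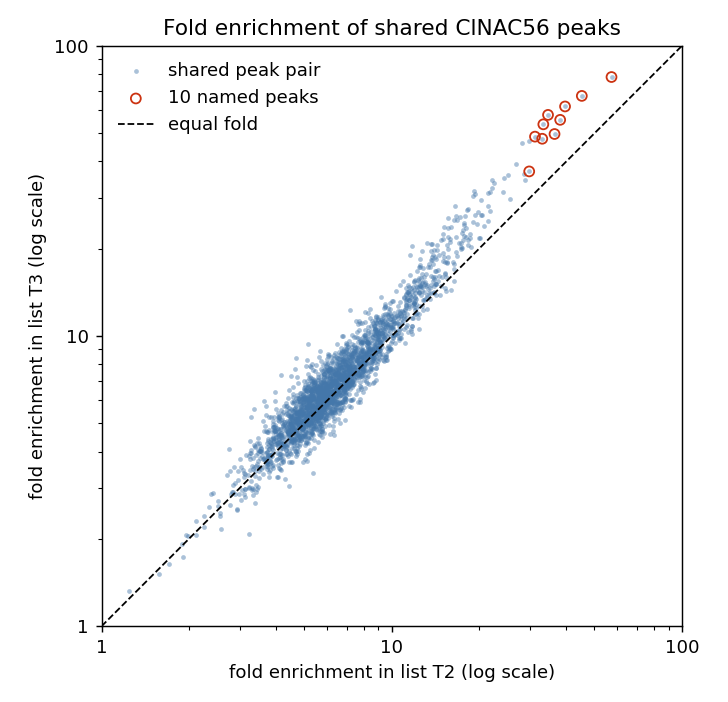
Fold enrichment of the 2490 overlapping peak pairs in list T2 (x axis) and list T3 (y axis), both on log scales; each point is a pair, open circles are the 10 named peaks and the dashed line marks equal folds. Points rise above the line toward high folds, and the 10 named peaks all lie above it.

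Ranked by the lower of the folds in T2 and T3, the strongest consensus site lay on chromosome 2 from 4138746 to 4139522, with a fold of 57.2 in T2 and 78.1 in T3. Its summit was covered by 1564 fragments in T2 (exact Poisson 95% interval 1487 to 1643) and 1926 in T3 (1841 to 2014), over a background of 5.14 and 5.05. A site on chromosome 4 from 15629665 to 15630413 followed, with folds of 45.2 and 67.3. Chromosome 10 held a pair of named sites less than 1 Mb apart. The site from 34460578 to 34461239 had folds of 39.6 and 61.9 with the identical summit, 34460895, in both lists. The site from 35031579 to 35032286 had folds of 36.4 and 49.7. Chromosome 3 held 3 of the 10 named sites. These ran from 1708811 to 1709523 (folds of 38.1 in T2 and 55.6 in T3), from 9279133 to 9279763 (33.3 and 53.7) and from 5771615 to 5772220 (29.8 and 36.9). The remaining sites lay on chromosome 11 from 26563258 to 26563941 (34.6 and 57.9), on chromosome 7 from 23667877 to 23668621 (33.0 and 47.9) and on chromosome 8 from 9570402 to 9571075 (31.2 and 48.7). At all 10 sites the fold was higher in T3, by a factor of 1.24 to 1.67, and the summits of both lists lay at most 17 bp apart. Which genes lie at these sites was not analysed here.

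Consensus sites occurred on all 11 assembled chromosomes. They numbered from 186 on chromosome 3 to 271 on chromosome 5. Taking the last peak end as the length of a chromosome, the density ran from 5.68 sites per Mb on chromosome 2 to 7.66 on chromosome 11. The lower of the fold enrichments in T2 and T3 had a median of 5.95 over the 2488 consensus sites, reached 10 or more at 311 and 20 or more at 33. Of the unassembled scaffolds, 3 T2 peaks and 1 T3 peak were on these sequences.

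**Figure D3:**
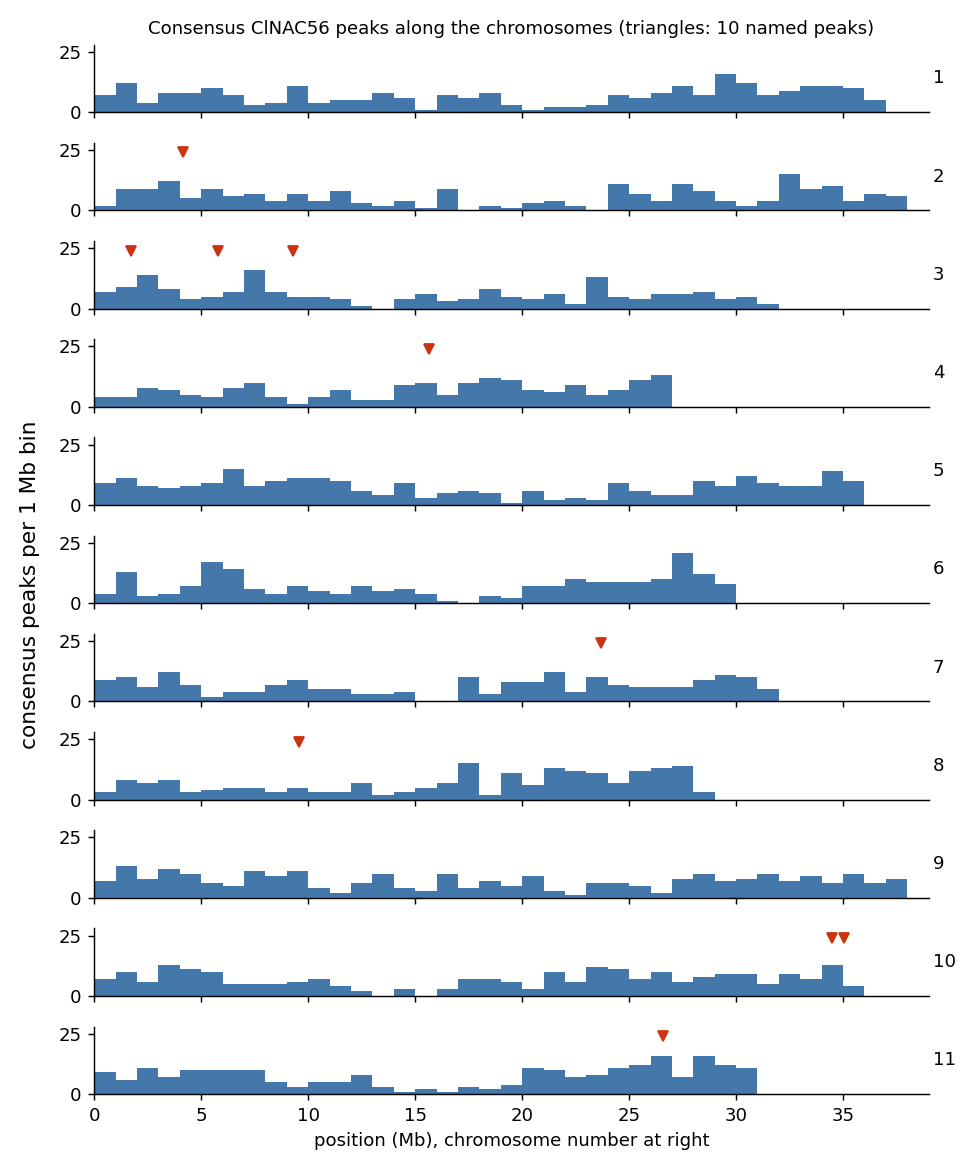
Number of consensus peaks (y axis) in bins of 1 Mb along each of the 11 chromosomes (x axis, position in Mb), with triangles at the 10 named peaks. Peaks occur on all 11 chromosomes, and the central 20% of the length held under 20% of the peaks on 11 of 11 chromosomes; chromosome 3 carries 3 of the triangles.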

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

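The share of peaks found in both lists stayed above chance under each alternative, at 85.8% to 88.8% for T2 and 74.3% to 76.9% for T3. The number of consensus sites was 1824 with a fold of at least 5 in both lists, 2470 with reciprocal 50% overlap and 3644 in the union, and leaving out a list left the 3288 or the 2846 peaks of the other. A −log10 q of at least 5 kept 2630 T2 and 3034 T3 peaks, and a fold of at least 5 kept 2009 and 2332. Spearman's rho of the folds stayed between 0.920 and 0.923, and with fragment numbers in place of folds it was 0.949. Single-list peaks remained weaker and narrower than shared peaks in both lists in all alternatives run, a difference that is partly built in, as stated above. The choice of strongest sites depended on the ranking measure. Of the 10 named sites, 9 were among the 10 strongest by mean fold, 6 by the lower −log10 q and 0 by the lower fragment number, a ranking that gives no weight to background. Sheet T1 repeats T3 and had been counted with it, so leaving it out tests nothing. The other settings meant for motifs, gene positions and target gene lists were not run, because no genome sequence or annotation was used. Counting error bears most on peaks with few fragments, and the fewest were 51 in T2 and 47 in T3. Of the weakest quartile of T3 peaks by fold, 50.9% was not shared. Whether counting error accounts for this was not tested.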

Other observations

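Apart from the row-by-row comparison of the sheets, which was fixed beforehand, the tests in this part were chosen after the lists had been seen. Consensus ClNAC56 sites were denser toward the chromosome ends. The first and last 20% of a chromosome's length together held 49.5% ± 4.35 (SD over 11 chromosomes) of its consensus sites, against 40% for even spacing. The share exceeded 40% on 11 of 11 chromosomes (exact two-sided sign-flip permutation p = 0.00098, the smallest that 11 chromosomes can give). The central 20% held 12.1% ± 3.08, against 20% for even spacing. Even spacing does not allow for differences in mappability or for gaps in the assembly, which were not examined. The pattern therefore may not be particular to ClNAC56. The lists taken singly and the sites of low background gave outer shares of 49.3% to 49.8%. Sites also lay near each other, since 371 of the 2488 (14.9%) had a neighbour within 10 kb, against a mean of 318.9 for random positions (one-sided permutation p = 0.021). After moving sites by up to 500 kb the mean was 351.6 (permutation p = 0.21), so no clustering beyond the regional density was shown.

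A small set of 22 consensus sites had a background over 10 times the lowest of the list, 21 of them in both lists and 1 in T3 only. Their folds were low, with a median of 2.42 in T2 and 2.35 in T3, against 6.12 and 6.57 for the remaining consensus sites, a difference that is partly built in because the background divides the fold. The site with the highest background, on chromosome 11 from 8308436 to 8309021, had folds of 1.24 and 1.32 over backgrounds of 599 and 559. Folds above 5 in both lists occurred at 2 of the 22 sites. The site on chromosome 6 from 7307785 to 7308124 had folds of 7.45 and 7.24 over backgrounds of 38.0 and 37.0. The site on chromosome 11 from 7770045 to 7770441 had folds of 6.41 and 6.98 over backgrounds of 236 and 223. Its summit held 6782 and 6376 fragments, numbers before scaling that are not on the scale of the background. These sites were chosen after their values were seen.

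Sheet T1 repeats sheet T3. A candidate explanation is that the T3 table was placed on both sheets, and 100% of the peak names on sheet T1 start with T3. All 3288 rows were identical between T1 and T3, and 0 between T2 and T3. Separate libraries that gave the same peaks are argued against by this identity, which covers position, pileup, p, fold and q in each row. The names argue against them too, since 0% of the names on sheet T1 start with T1. On sheets T2 and T3, 100% start with the name of their own sheet. A peak list named T1 was not analysed here, and no biological explanation was tested.

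List T3 held 442 more peaks than list T2 and higher folds at strong sites. A deeper ClNAC56 library behind T3 is argued against, since the pileup scaling puts the T3 library at 0.914 times the size of the T2 library if both used a control of the same size. Another control library behind each list is argued against too. Of the 143 summits at the identical position in both lists, 11 had the lowest background in both and 7 had backgrounds from windows of different size. At the remaining 125 the recovered control counts were equal at 122 (97.6%), against 7.20% for independent Poisson counts of the same means. With the 7 counted as unequal the share was 92.4%. Among pairs called in both lists, a constant factor is argued against by the fold ratio of 1.14 (1.13 to 1.16) in the strongest quartile, above the interval of 1.06 to 1.09 in the third quartile. Single-list peaks, with folds up to 6.97 in T2 and 7.63 in T3, have no ratio. Their absence may account for part of this difference. What gave T3 its higher folds remains open, and no biological explanation was tested.

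Summit pileups were high for tags counted once per position. With single-end tags limited to 1 per position and strand, a summit could be covered by at most 608 fragments in T2 and 598 in T3. This takes the shortest peak width, 304 bp in T2 and 299 bp in T3, as the fragment length on each of 2 strands. The fragment length itself is not given in the sources used here, so the counts of peaks above the limit depend on this choice. That limit was exceeded at 56 T2 and 76 T3 peaks, 132 in all, of which 39 and 57 had a background of at most 10 times the lowest. The maximum, at the chromosome 11 site from 7770045 to 7770441 described above, was 11.2 times the limit in T2 and 10.7 times in T3. Among peaks of low background it was 4.81 and 5.93 times. Paired-end fragments, or duplicates kept in the counts, remain open, since the library layout and the treatment of duplicates are not given in the sources used here. If duplicates were kept, the counting intervals of the strong sites would be too narrow.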
